A study of Mus musculus with 4 samples.

How the data were processed

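Cells of the adult mouse mammary gland were sorted by flow cytometry and profiled by droplet-based single-cell RNA sequencing with the 10x Chromium 3′ v2 chemistry, which counts unique molecular identifiers (UMIs) at the 3′ ends of transcripts. Per the labels, the series holds 4 libraries from C57BL/B6 mice: a control and a Zeb1 MSKO library at 8 weeks (replicate 1) and a control and a Zeb1 MSKO library at 9 weeks (replicate 2). The labels do not expand MSKO and do not state which part of Zeb1 was deleted. Each capture aimed at 10000 cells and the sequencing at about 50000 reads per cell, per the labels' protocols. The markers used for the sort are not given in the sources used here.

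The deposited matrix holds raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 2.1.0 and the mm10 genome build, per the submitters' processing notes. It aggregates all 4 libraries, with 36884 barcodes over 27998 genes, and the barcode suffix names the library. Whether the libraries were brought to equal depth before aggregation is not given in the sources used here; the median count per barcode still ranged from 6376 to 10529.5 UMIs, and no barcode had fewer than 2566 UMIs. Gene coordinates were taken from GENCODE vM21, which uses the same assembly as mm10, and 27645 of the 27998 genes were matched by identifier.

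Cells with at least 500 detected genes and at most 10% mitochondrial counts were kept. Doublets were called within each library by a nearest-neighbour score against simulated doublets (2 simulated per cell, 2000 variable genes, 30 components), with an assumed rate of 8%. The procedure called 1891 doublets (4.64% and 4.05% of the control and Zeb1 MSKO barcodes at 8 weeks, 5.00% and 6.78% at 9 weeks) and recovered 61.7%, 49.8%, 62.0% and 65.1% of the simulated doublets in the same order, so some doublets remain. After both filters, 34588 cells were kept and 2296 removed. Counts were scaled per cell and log transformed, reduced to 30 principal components of 2000 variable genes, joined to 15 nearest neighbours and grouped by the Leiden algorithm at resolution 1 into 26 clusters, without correction between libraries. Clusters were named from 15 marker lists fixed in advance: a name needed at least 3 detected markers, a mean excess of 1.5 on the log2 scale over other clusters and a margin of 1 over the next list. The marker lists were fixed before the data were examined, and these scoring limits afterwards. Of the 26 clusters, 5 were basal-like, 5 luminal progenitor-like, 5 hormone-sensing luminal-like, 3 fibroblast-like, 3 endothelial-like and 1 T or NK-like, and 4 stayed unnamed.

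UMI counts were summed per library and class, so that the library was the replicate (n = 2 per genotype). The main test was edgeR's quasi-likelihood test with TMM scaling and edgeR's default filter on low counts, Zeb1 MSKO against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the genotype effect between classes was tested as an interaction with the library as a block. CPM values are UMI counts scaled to the library's total in the class, with TMM scaling where a mean and SD are given. Fold changes of genes are edgeR estimates with their standard errors, and fold changes within 1 age are log2 ratios with a prior count of 2. In each class 23 gene lists fixed in advance were tested with camera (limma) on log2 CPM at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Shares of cells were compared by a two-sided exact permutation test over libraries, for which the smallest p that 2 against 2 libraries allow is 0.333. For the share of basal-like cells with luminal keratins each cell was thinned to 2000 UMIs, a depth that every kept cell exceeded. Wilson 95% intervals of shares and the floor of 3 counts used for undetected genes cover counting error only.

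The replicate number stands for the age in the labels. The 9 against 8 week log2 ratios of the control and of the Zeb1 MSKO libraries were correlated across genes (Pearson r 0.319 in basal-like, 0.279 in luminal progenitor-like and 0.232 in hormone-sensing luminal-like cells; genes are not independent replicates), while the Zeb1 MSKO to control ratios at 8 and at 9 weeks had r of -0.376, -0.192 and -0.00625. A fit with age as a block was run beside the fit without it. The block leaves 1 residual degree of freedom, so its p-values rest largely on the spread that edgeR shares across genes. The same holds for the age comparison with genotype as a block. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these 4 libraries, which may be partly technical. Each age has 1 library per genotype, so a difference between ages cannot be separated from a difference between preparations or sequencing batches.

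Named genes follow a rule fixed in advance. Among called genes with a mean of at least 10 CPM and the same direction at both ages, the 10 largest changes in each direction were taken, and within each fixed list the called members with the smallest p. Where fewer than 5 genes of a class were called, its 10 genes with the smallest p and up to 2 members per list were given as values only. Unnamed gene models, ribosomal protein genes and pseudogenes were left out by that rule.

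The tests were tried on simulated counts drawn from the real libraries' means, with 200 genes changed 2-fold or 8-fold in each of 10 simulations. Only genes with a mean of at least 10 CPM were changed. For the basal-like genotype comparison (12726 genes) edgeR recovered 98.6% of 8-fold and 5% of 2-fold changes, with 98 false among 1134 calls. For luminal progenitor-like cells (12607 genes) it recovered 99.8% and 6.9%, with 138 false among 1205 calls, and for hormone-sensing luminal-like cells (12808 genes) 98.6% and 4.2%, with 143 false among 1171 calls. DESeq2 made 272 false among 1419, 325 among 1514 and 507 among 1716 calls in the same order. The basal minus luminal progenitor interaction (11963 genes) recovered 75.7% of 8-fold changes and the basal minus hormone-sensing luminal one (11906 genes) 68.4%. In the simulated basal-like list test (12920 genes), camera at the preset correlation called the changed list in 10 of 10 simulations and 5 of 220 unchanged ones. With an estimated correlation it called the changed list in 0 of 10. The simulated genes were drawn independently of each other, so these rates do not cover lists whose genes vary together between libraries. Counts were drawn with edgeR's dispersion of each gene and no further spread, so the recovery rates may not hold in the real data. In real hormone-sensing luminal-like cells Wfdc12 and Sbp differed by over 8-fold without passing edgeR's adjusted threshold.

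Alternatives fixed in advance were DESeq2, RLE size factors, no filter on low counts, age as a block, no doublet removal, all deposited barcodes, classes by marker score, cells thinned to 2000 UMIs, clusters at resolution 2, other denominators and leaving out each library in turn. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.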

Results

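Single-cell transcriptomes of sorted mammary gland cells were obtained from control and Zeb1 MSKO mice to compare the make-up and gene expression of the mammary epithelium. Zeb1 encodes a zinc-finger transcription factor known as a repressor of epithelial junction genes. The 4 libraries, 1 per genotype at each of 8 and 9 weeks of age, held 9790 (control, 8 weeks), 9693 (Zeb1 MSKO, 8 weeks), 7627 (control, 9 weeks) and 9774 (Zeb1 MSKO, 9 weeks) barcodes. Their total counts were 103331868, 80853204, 87797283 and 122122443 UMIs in the same order. The median barcode held 9403, 6376, 10214 and 10529.5 UMIs. After filtering, 9220, 9226, 7176 and 8966 cells remained. The Zeb1 MSKO library at 8 weeks was thus the shallowest per cell and its counterpart at 9 weeks the deepest.

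Zeb1 (ENSMUSG00000024238, mm10 chromosome 18, 5591860 to 5775467, plus strand) was detected mainly outside the epithelium. Fibroblast-like cells held 184, 307, 17 and 14 Zeb1 UMIs in the control and Zeb1 MSKO libraries at 8 weeks and the control and Zeb1 MSKO libraries at 9 weeks, that is 57.3, 74.2, 85.1 and 51.0 CPM. Endothelial-like cells reached 64.0, 79.1, 36.1 and 62.0 CPM. Basal-like cells held 4, 15, 0 and 3 UMIs in the same order. These were 0.27, 0.50, 0 and 0.14 CPM, where 3 counts correspond to 0.199, 0.1, 0.158 and 0.135 CPM. Luminal progenitor-like cells held 11, 10, 3 and 32 UMIs (0.29, 0.69, 0.12 and 1.12 CPM) and hormone-sensing luminal-like cells 6, 6, 4 and 4 (0.17, 0.36, 0.11 and 0.07 CPM). In basal-like and luminal progenitor-like cells the value of the Zeb1 MSKO library was thus above that of its control at both ages (edgeR adjusted p = 1 in luminal progenitor-like cells; not tested in basal-like cells, where the filter on low counts removed Zeb1). Because the deleted part of the gene is not stated and reads come from the 3′ end, these counts do not check the genotype labels. Zeb2, the paralog of Zeb1, showed 8, 22, 1 and 6 UMIs in basal-like cells against 122, 130, 145 and 168 CPM in fibroblast-like cells.

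The epithelium consisted of basal-like cells (contractile myoepithelial and basal keratin genes such as Acta2, Tagln and Krt14), luminal progenitor-like cells (Csn3, Ltf, Wfdc18) and hormone-sensing luminal-like cells (Prlr, Areg, Cited1). Basal-like cells made up 21.7% of epithelial cells in the control and 64.1% in the Zeb1 MSKO library at 8 weeks (Wilson 95% intervals 20.8 to 22.6 and 63.0 to 65.1), but 29.5% and 27.9% at 9 weeks (28.5 to 30.6 and 27.0 to 28.9). Luminal progenitor-like cells made up 47.7% and 21.3% at 8 weeks and 37.5% and 36.0% at 9 weeks. Hormone-sensing luminal-like cells made up 30.7% and 14.6% at 8 weeks and 33.0% and 36.1% at 9 weeks. The sort can set these shares.

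The mean basal-like share was 25.6% ± 5.55 in control and 46.0% ± 25.6 in Zeb1 MSKO libraries (SD, n = 2 each; exact permutation test, two-sided p = 0.667). The luminal progenitor-like share was 42.6% ± 7.20 against 28.6% ± 10.4 (n = 2 each; exact permutation p = 0.333, the smallest this design allows), and the hormone-sensing luminal-like share 31.8% ± 1.64 against 25.3% ± 15.2 (n = 2 each; exact permutation p = 1). The basal-like and hormone-sensing luminal-like shares differed by less than the spread between libraries, and the luminal progenitor-like share was lower in both Zeb1 MSKO libraries than in both controls. Without the Zeb1 MSKO library at 8 weeks the differences of the 3 classes were 2.36, -6.60 and 4.24 percentage points. The cluster with the most cells of a class differed between libraries. In basal-like cells it was cluster 0 in both libraries at 8 weeks (49.0% of the class in control and 76.9% in Zeb1 MSKO) and cluster 1 in both at 9 weeks (91.1% and 87.6%). Luminal progenitor-like cells lay mainly in clusters 2 (82.7%), 9 (54.7%), 5 (69.5%) and 3 (75.5%), and hormone-sensing luminal-like cells in clusters 6 (93.1%), 10 (85.5%), 7 (94.5%) and 4 (97.9%), in the same order of libraries. Fibroblast-like cells were 4.49% and 6.10% of all cells at 8 weeks against 0.348% and 0.368% at 9 weeks, and 111, 494, 17 and 16 cells stayed in unnamed clusters.

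**Figure D1:**
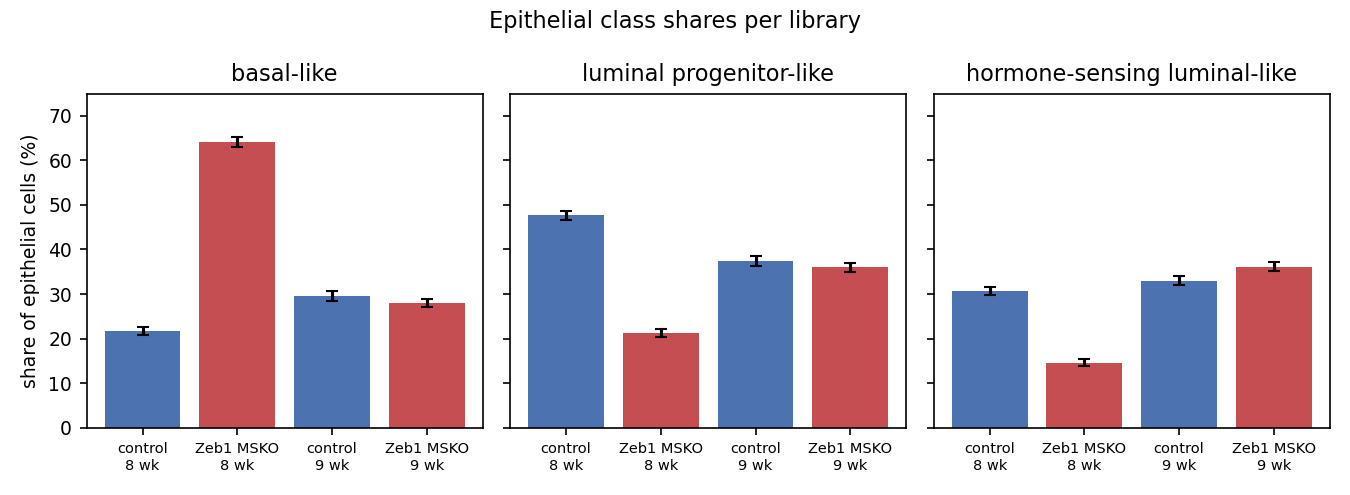
Share of epithelial cells (%) in the basal-like, luminal progenitor-like and hormone-sensing luminal-like classes for each of the 4 libraries, with Wilson 95% intervals that cover counting error only. The basal-like share of the Zeb1 MSKO library at 8 weeks, 64.1%, stands above the other libraries, which lie between 21.7% and 29.5%.

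In basal-like cells, Krt15, a basal keratin, was at 750 ± 161 CPM in control and 320 ± 5.11 CPM in Zeb1 MSKO libraries (SD, n = 2 each; log2 fold change -1.23, SE 0.27), lower at both ages. Coch, an extracellular matrix protein known from the inner ear, was at 10.8 ± 3.71 against 1.70 ± 0.958 CPM (-2.67, SE 0.52), and Igfbp5, an insulin-like growth factor binding protein, at 880 ± 50.8 against 1573 ± 77.3 CPM (0.84, SE 0.22). Plac8 was at 2.34 ± 1.25 against 10.8 ± 3.31 CPM. No gene of the 12920 tested passed edgeR's adjusted threshold (adjusted p = 1 for Krt15, Coch, Igfbp5 and Plac8). At an unadjusted p under 0.05 there were 50 genes, and DESeq2 called 1, Coch (DESeq2 adjusted p = 0.0302). With age as a block, a fit that leaves 1 residual degree of freedom, edgeR called 12 genes (5 higher and 7 lower in Zeb1 MSKO). Among them were Coch (edgeR adjusted p = 1.04e-06), Plac8 (0.000229) and Krt15 (0.0296). Across all tested genes the genotype log2 ratios at 8 and 9 weeks had a Pearson r of -0.376 in basal-like, -0.192 in luminal progenitor-like and -0.00625 in hormone-sensing luminal-like cells, and 33.5%, 42.0% and 51.4% of genes had the same sign at both ages (genes are not independent replicates).

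Among the lists, the myoepithelial contractile genes, which include smooth muscle actin and its regulators, were lower in Zeb1 MSKO basal-like cells, with 14 of 17 members below 0 and a median log2 fold change of -0.22 (camera adjusted p = 0.00149; adjusted p = 0.969 with an estimated correlation). This came mainly from 8 weeks, with a list median log2 ratio of -0.41 there and -0.06 at 9 weeks, and 9 of 17 members lower at both ages. The summed level of the list went from 23158 to 14041 CPM at 8 weeks and from 25134 to 25544 CPM at 9 weeks. Tagln, an actin-binding protein of smooth muscle, was at 3889 ± 124 against 2854 ± 1192 CPM (n = 2 each), with log2 ratios of -0.98 at 8 weeks and -0.04 at 9 weeks. Estrogen and progesterone response genes were higher (14 of 16 positive, median 0.28, camera adjusted p = 0.0116; adjusted p = 0.969 with an estimated correlation). Their median log2 ratios were 0.23 at 8 weeks and 0.11 at 9 weeks, with 4 of 16 members higher and 0 lower at both ages. The summed level went from 1034 to 1389 CPM at 8 weeks and from 791 to 751 CPM at 9 weeks. Markers of cell types were also called, but some of them are members of these same lists. The basal markers share Acta2, Myh11, Mylk, Cnn1, Actg2 and Oxtr with the contractile list. The hormone-sensing luminal markers share Prlr, Esr1, Pgr, Areg, Cited1 and Tnfsf11 with the estrogen and progesterone list. These calls are therefore not independent of the list results. Of the basal markers 8 of 10 were negative (median -0.22, camera adjusted p = 0.0226), of the hormone-sensing luminal markers 8 of 9 positive (median 0.28, 0.0226) and of the macrophage or dendritic markers 4 of 6 positive (median 0.55, 0.0249), each at adjusted p = 0.636 with an estimated correlation. G2 and M phase genes were called lower (camera adjusted p = 0.0465; adjusted p = 0.969 with an estimated correlation) although their median was -0.05 and their mean 0.03, and their medians within each age were -2.19 and 1.49. The epithelial junction and splicing genes, a class that Zeb1 is known to repress, had a median of -0.03 with 10 of 27 positive (camera adjusted p = 0.891), and mesenchymal genes a median of -0.04 with 10 of 21 positive (0.968). Ovol1, an epithelial transcription factor, was at 12.6 ± 2.34 against 6.10 ± 3.05 CPM and Vim, the mesenchymal intermediate filament, at 565 ± 37.2 against 390 ± 73.2 CPM (n = 2 each), neither past the test. No list member was called over all genes tested, and adjusted over the list alone 1 was (Krt15, lower). The latter count was 5 with age as a block, 10 and 26 without the Zeb1 MSKO library at 8 or at 9 weeks, and 0 without either control library. In all 3 lists were called, against 7 with age as a block and 7 without the Zeb1 MSKO library at 9 weeks.

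In luminal progenitor-like cells, Angptl4, an inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830), was at 16.0 ± 0.151 CPM in control and 49.6 ± 6.18 CPM in Zeb1 MSKO libraries (SD, n = 2 each; log2 fold change 1.64, SE 0.26). The metallothionein Mt2 was at 295 ± 3.48 against 97.1 ± 25.5 CPM (-1.60, SE 0.29), the antioxidant enzyme Srxn1 at 62.1 ± 1.98 against 24.5 ± 1.87 CPM (-1.34, SE 0.25), the kallikrein protease Klk10 at 8.60 ± 2.94 against 1.67 ± 0.0701 CPM and the water channel Aqp1 at 21.3 ± 15.8 against 1.83 ± 0.347 CPM. Dclk1, a microtubule-associated kinase, was at 43.7 ± 4.40 against 95.6 ± 20.3 CPM. Each of these genes had the same direction at both ages, and none passed edgeR's adjusted threshold (adjusted p = 1 each). Of the 12801 genes tested edgeR called 0, with 178 at an unadjusted p under 0.05. DESeq2 called 7 (3 higher, 4 lower), including Aqp1 (DESeq2 adjusted p = 2.95e-05), Angptl4 (0.000845), Mt2 (0.00251), Klk10 (0.00608) and Srxn1 (0.0129). With no filter on low counts edgeR called 82 genes (42 higher, 40 lower). Most of these genes were also tested with the filter, where none was called. Examples are Csn1s2a (log2 fold change without the filter 3.11) and Csn2 (3.03), higher, and Csf3 (-2.54) and Aqp1 (-3.53), lower. The higher ones also included hair-follicle keratins (Krt71, Krt25, Krt28), which the filter had removed, and the lower ones S100a8 and S100a9, leading genes of an unnamed immune cluster. Krt71 was at 0.03, 14.45, 0 and 0.04 CPM in luminal progenitor-like cells of the control and Zeb1 MSKO libraries at 8 weeks and those at 9 weeks. In unnamed clusters of the Zeb1 MSKO library at 8 weeks it was at 1369 CPM.

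Of the 23 lists, 12 were called in luminal progenitor-like cells, 10 higher and 2 lower in Zeb1 MSKO. Wnt pathway genes had a median log2 fold change of 0.53 with 24 of 29 positive (camera adjusted p = 4.85e-07; adjusted p = 0.550 with an estimated correlation, the lowest of any list in this class). Hedgehog pathway genes had a median of 0.68 with 7 of 7 positive (camera adjusted p = 0.000519; adjusted p = 0.550 with an estimated correlation). Myoepithelial contractile genes had a median of 0.51 (12 of 15 positive, camera adjusted p = 6.31e-05), with Oxtr, the oxytocin receptor, at 8.18 ± 4.42 against 33.5 ± 17.8 CPM (n = 2 each). Extracellular matrix genes had a median of 0.58 (22 of 23 positive, 9.55e-05), both lists at adjusted p = 0.573 with an estimated correlation. YAP and TAZ targets had a median of 0.32 (20 of 22 positive) and TGF-beta and BMP pathway genes 0.38 (18 of 22 positive), both at adjusted p = 0.550 with an estimated correlation. Zeb1 partner genes (0.21; adjusted p = 0.573 with an estimated correlation) and basal keratins and adhesion (0.45), mesenchymal (0.36) and immediate early genes (0.29; adjusted p = 0.683 with an estimated correlation for these 3) were also called higher. G2 and M phase genes were lower, with 0 of 25 positive and a median of -1.18 (camera adjusted p = 4.15e-10; adjusted p = 0.573 with an estimated correlation). Interferon response genes had a median of -0.39 with 3 of 25 positive (7.13e-05; adjusted p = 0.573 with an estimated correlation). Oas1a, an interferon-induced gene, was at 4.39 ± 0.162 against 0.985 ± 0.197 CPM (n = 2 each). No member of any list was called over all genes tested. Adjusted over the list alone the count was 0, but 10 with age as a block, 8 and 11 without the Zeb1 MSKO library at 8 or at 9 weeks, and 30 without the control library at 9 weeks.

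Several of these medians came mainly from 8 weeks. In luminal progenitor-like cells the extracellular matrix median was 0.81 at 8 weeks and 0.02 at 9 weeks, the contractile median 1.18 and 0.09, and the G2 and M phase median -2.67 and 0.55. The Wnt (0.67 and 0.30), Hedgehog (0.43 and 0.66) and interferon medians (-0.26 and -0.38) had 1 direction. Markers of other cell types went with them, although the basal markers share members with the contractile and the basal keratin and adhesion lists. Of the basal markers 10 of 10 were positive (median 0.90, camera adjusted p = 7.37e-08; adjusted p = 0.746 with an estimated correlation), and of the fibroblast markers 8 of 8 (median 1.30, camera adjusted p = 0.230). Krt14, a basal keratin, was at 37.1, 192, 42.7 and 34.5 CPM in luminal progenitor-like cells of the control and Zeb1 MSKO libraries at 8 weeks and those at 9 weeks, and at 53.9, 245, 25 and 7.29 CPM in fibroblast-like cells. Without the Zeb1 MSKO library at 8 weeks, 2 lists were called in this class.

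**Figure D2:**
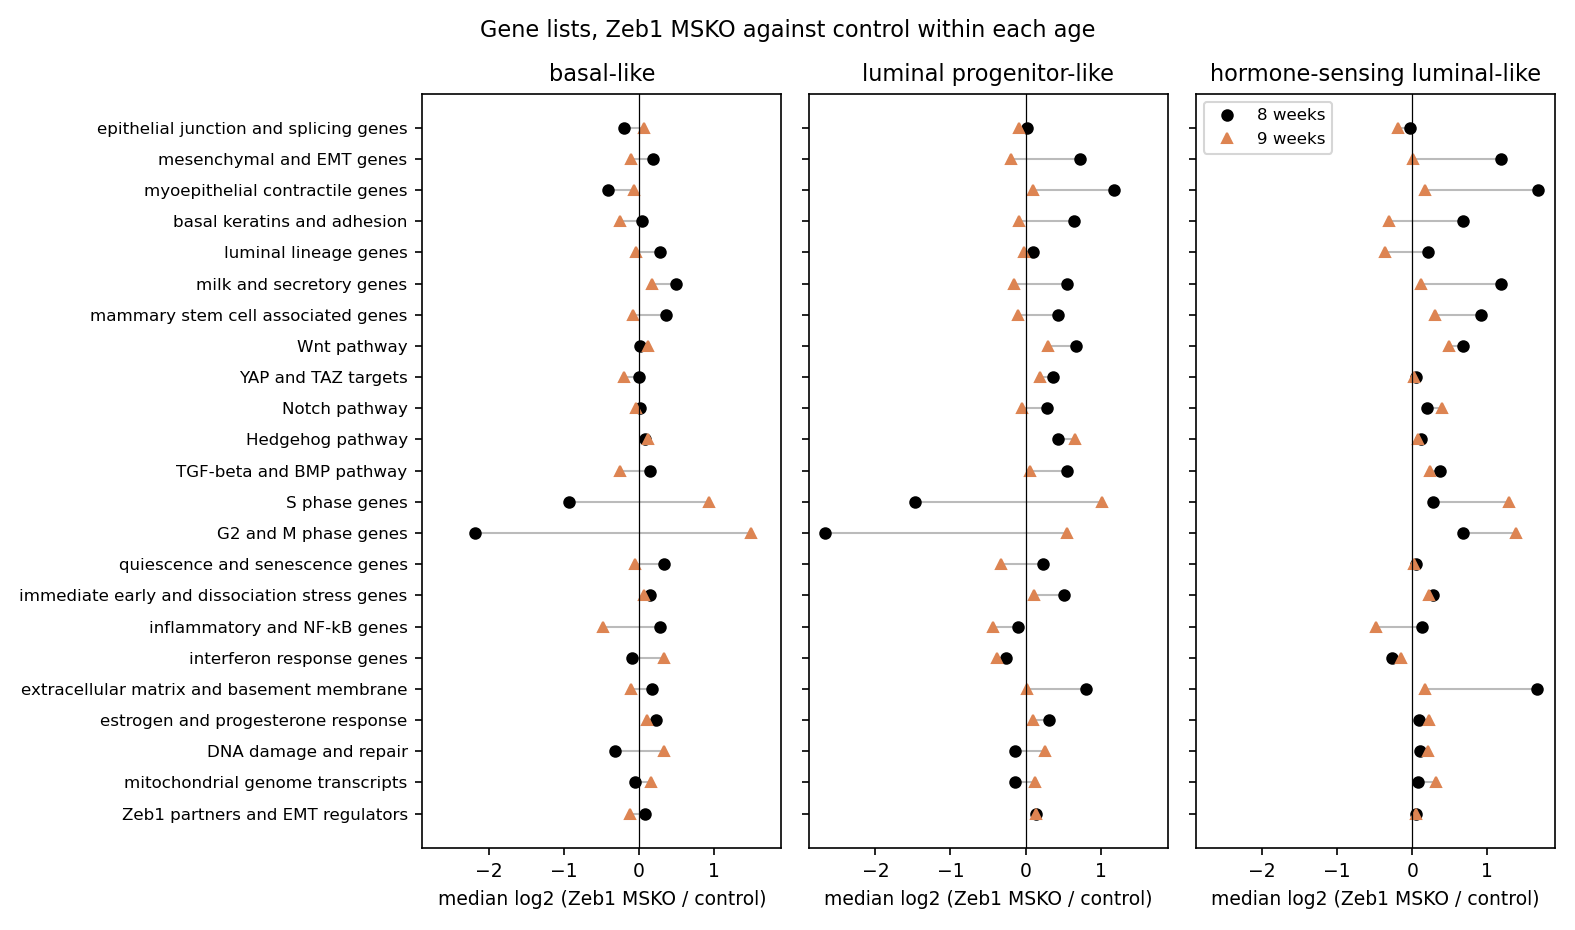
Median log2 ratio of Zeb1 MSKO to control over the measured members of each of the 23 gene lists, within 8 weeks (circles) and within 9 weeks (triangles), for the 3 epithelial classes. G2 and M phase genes lie at -2.19 and 1.49 in basal-like and at -2.67 and 0.55 in luminal progenitor-like cells, and at 0.68 and 1.39 in hormone-sensing luminal-like cells.

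In hormone-sensing luminal-like cells, Wfdc12, a whey acidic protein family protease inhibitor (chromosome 2, 164189231 to 164190608), was at 3.65 ± 0.763 CPM in control and 36.6 ± 6.45 CPM in Zeb1 MSKO libraries (SD, n = 2 each; log2 fold change 3.32, SE 0.28; edgeR adjusted p = 0.735). Sbp, which encodes spermine binding protein (chromosome 17, 23941672 to 23945607), was at 147 ± 93.0 against 0.726 ± 0.442 CPM (-7.53, SE 0.75; edgeR adjusted p = 0.751), and Dcpp3, in the same region of chromosome 17 (23917458 to 23919441), at 9.12 ± 3.11 against 0.0296 ± 0.0418 CPM. Hepacam2 was at 3.57 ± 1.96 against 51.9 ± 27.0 CPM, the mucin Muc16 at 8.07 ± 0.596 against 0.292 ± 0.256 CPM, and Fxyd6, a regulator of the sodium pump, at 106 ± 14.1 against 41.2 ± 0.314 CPM. Trpc6, a cation channel, was at 13.3 ± 0.461 against 3.54 ± 0.762 CPM, and the atypical cadherin Cdh13 at 51.1 ± 27.8 against 5.51 ± 2.24 CPM. Each had the same direction at both ages. edgeR called 0 of 13059 genes, with 466 at an unadjusted p under 0.05, and DESeq2 called 40 (20 higher, 20 lower), among them Sbp (DESeq2 adjusted p = 1.91e-32), Wfdc12 (1.08e-17) and Cdh13 (7.86e-07). With age as a block edgeR called 1 gene, Sbp (edgeR adjusted p = 0.0155), and without the control library at 8 weeks 1 gene.

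**Figure D3:**
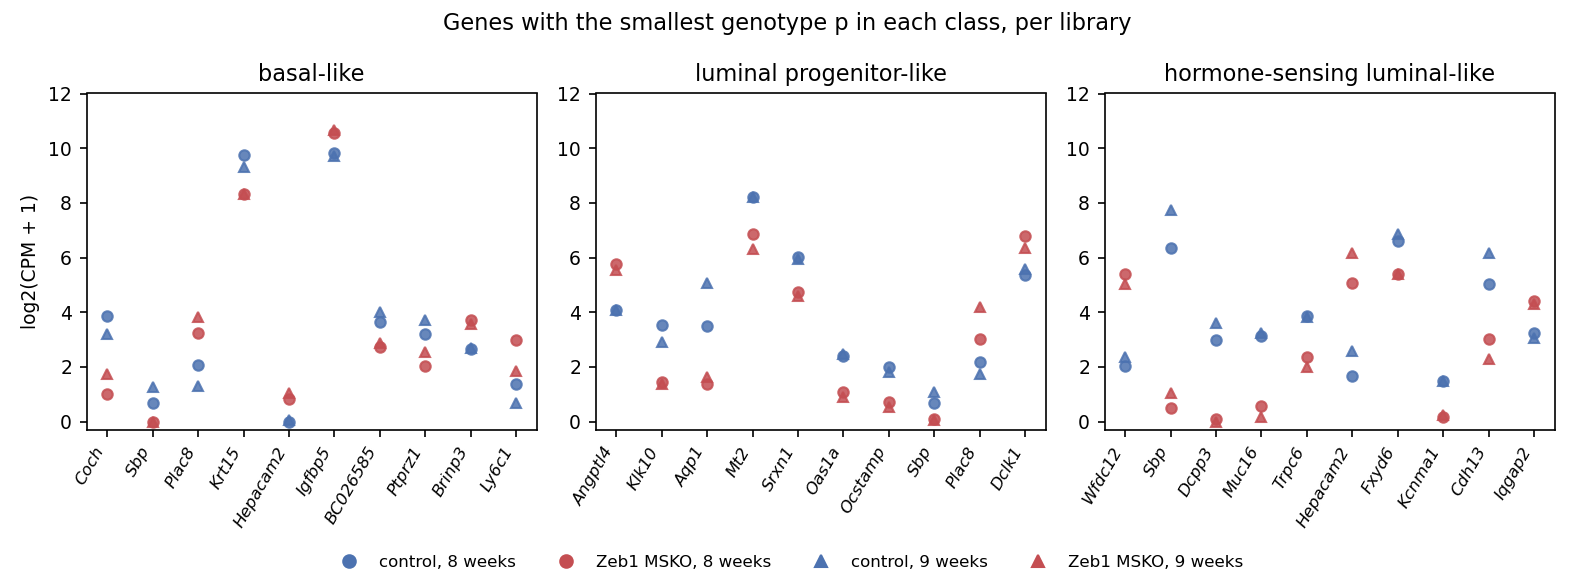
Levels, as log2(CPM + 1), of genes with small p-values in the comparison of Zeb1 MSKO with control libraries, in each epithelial class. Each point is 1 library, coloured by genotype and shaped by age; none of these genes passed edgeR's adjusted threshold, and Wfdc12 in hormone-sensing luminal-like cells was at 3.65 against 36.6 CPM.

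In the same cells 11 lists were called, 9 higher and 2 lower in Zeb1 MSKO. G2 and M phase genes had a median log2 fold change of 1.30 with 19 of 22 positive (camera adjusted p = 5.66e-11; adjusted p = 0.599 with an estimated correlation, the lowest of any list in this class). S phase genes had a median of 0.85 with 22 of 24 positive (1.1e-08; adjusted p = 0.599 with an estimated correlation). Both lists had positive medians at both ages. Birc5, a mitotic survivin, was at 1.31 ± 0.268 against 5.88 ± 2.30 CPM (n = 2 each; DESeq2 adjusted p = 0.0204). Milk and secretory genes had a median of 0.84 (14 of 15 positive, camera adjusted p = 4.93e-05; adjusted p = 0.599 with an estimated correlation). Lcn2, an iron-siderophore binding protein, was at 45.4 ± 11.2 against 96.5 ± 4.76 CPM and the milk fat globule protein Mfge8 at 51.7 ± 0.969 against 111 ± 28.7 CPM (n = 2 each). Adjusted over the list alone 4 of the 15 members were higher, against 0 over all genes tested. Over all 23 lists that count was also 4, but 7 with age as a block, 45 and 36 without the Zeb1 MSKO library at 8 or at 9 weeks, and 0 without either control library. Extracellular matrix (median 1.34, 23 of 24 positive), myoepithelial contractile (0.94), mammary stem cell associated (1.01), Wnt (0.62), TGF-beta and BMP (0.51) and mitochondrial genome genes (0.16) were also called higher. The first and the last of these were at adjusted p = 0.613 with an estimated correlation and the others at adjusted p = 0.599 with an estimated correlation. Interferon response genes (-0.23) and epithelial junction and splicing genes (-0.13, camera adjusted p = 0.0330) were called lower, both at adjusted p = 0.599 with an estimated correlation. With the milk and secretory genes, 8 of 10 luminal progenitor markers were positive (median 0.51, camera adjusted p = 0.00846; adjusted p = 0.790 with an estimated correlation). The luminal progenitor markers share members with the milk and secretory list, and the basal markers with the contractile list, so these results are not independent. Also, 10 of 10 basal markers (median 1.26, camera adjusted p = 2.2e-06; adjusted p = 0.790 with an estimated correlation) and 8 of 8 fibroblast markers (median 1.51, camera adjusted p = 0.278) were positive. The extracellular matrix and contractile medians were 1.66 and 1.68 at 8 weeks against 0.17 and 0.17 at 9 weeks. Without the Zeb1 MSKO library at 8 weeks 2 lists were called, and without the control library at 9 weeks 7. fry called 0 lists in any of the 3 classes.

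Whether the genotype effect differed between classes was tested directly. Between basal-like and luminal progenitor-like cells edgeR called 0 of 13869 genes, with 400 at an unadjusted p under 0.05. No other tool was run for interactions. Between basal-like and hormone-sensing luminal-like cells it called 1 of 14150, Cdh13 (ENSMUSG00000031841, chromosome 8, 118283733 to 119324921), with a log2 difference of 3.16 (SE 0.34, edgeR adjusted p = 0.0352). Cdh13 was at 26.6, 42.5, 50.2 and 30.7 CPM in basal-like and at 31.9, 7.13, 72 and 3.98 CPM in hormone-sensing luminal-like cells of the control and Zeb1 MSKO libraries at 8 weeks and those at 9 weeks. The call was lost with classes by marker score (adjusted p = 0.0686), and leaving out the control or Zeb1 MSKO library at 8 weeks or those at 9 weeks gave 20, 71, 22 and 397 called genes.

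Krt8 and Krt18, the keratins of luminal cells, were detected after thinning in 82.0% and 83.6% of basal-like cells of the control and Zeb1 MSKO libraries at 8 weeks and in 80.5% and 66.4% at 9 weeks. The means were 81.2% ± 1.06 and 75% ± 12.2 (n = 2 each; exact permutation test, two-sided p = 1). The same share in fibroblast-like cells, which should lack these keratins, was 43.2%, 50.8%, 60% and 18.2%. Median depths were 7320.5, 6971, 8051 and 7905 UMIs in fibroblast-like and 7695, 5457, 8008.5 and 7865 UMIs in basal-like cells. Without thinning the basal-like shares were 98.8%, 98.4%, 99.1% and 96.7%. The difference between genotypes lay within the spread between libraries. At this limit of at least 1 UMI, the library with the lowest share in basal-like cells also had the lowest share in fibroblast-like cells. The libraries at 9 weeks held only 25 and 33 fibroblast-like cells. At a limit of at least 2 UMIs the lowest shares fell in different libraries. They were 55.0%, 56.7%, 52.0% and 33.6% in basal-like and 12.1%, 16.3%, 0% and 6.06% in fibroblast-like cells.

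The other labelled factor, age, was compared in the same libraries. In basal-like cells Cebpb, a transcription factor of mammary differentiation and inflammation (chromosome 2, 167688915 to 167690418), fell from 2580 ± 680 CPM at 8 weeks to 24.7 ± 4.34 CPM at 9 weeks (SD, n = 2 each; log2 fold change -6.71, SE 0.29; edgeR adjusted p = 0.000385). Id4, an inhibitor of basic helix-loop-helix factors (chromosome 13, 48261228 to 48266026), fell from 208 ± 12.8 to 13.6 ± 6.05 CPM (-3.93, SE 0.34; edgeR adjusted p = 0.00482). Igfbp3, a growth factor binding protein, fell from 896 ± 177 to 155 ± 9.45 CPM (-2.53), the activin antagonist Fst from 492 ± 92.2 to 129 ± 42.7 CPM (-1.94) and the Notch ligand Jag1 from 79.9 ± 17 to 26.6 ± 3.43 CPM (-1.59). Socs3, a feedback inhibitor of cytokine signalling, rose from 230 ± 0.809 to 617 ± 108 CPM (1.43, SE 0.20; edgeR adjusted p = 0.0257), and the intermediate filament gene Synm from 20.3 ± 4.01 to 51.5 ± 5.89 CPM (1.34). edgeR called 191 of 12920 genes, 11 higher and 180 lower at 9 weeks, and DESeq2 666 (123 higher, 543 lower). With genotype as a block edgeR called 544 (96 higher, 448 lower). Leaving out the control or Zeb1 MSKO library at 8 weeks gave 1021 and 319 genes, and leaving out those at 9 weeks 1536 and 104.

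Among inflammatory and NF-kB genes in basal-like cells 18 of 22 were lower at 9 weeks (median -0.93, camera adjusted p = 4.32e-05; adjusted p = 0.582 with an estimated correlation). The 3 called lower were the chemokine genes Cxcl1 (576 ± 180 to 91.4 ± 5.53 CPM) and Cxcl2 (108 ± 33.2 to 5.63 ± 5.45 CPM) and the adhesion molecule Icam1 (715 ± 3.13 to 277 ± 64.4 CPM). Adjusted over the list alone, 10 were lower. Stromal markers went with this list in basal-like cells, with 6 of 8 fibroblast markers below 0 (median -1.54, 2 called, camera adjusted p = 0.0105; adjusted p = 0.688 with an estimated correlation) and 4 of 4 endothelial markers (median -1.63, 2 called, camera adjusted p = 0.00181; adjusted p = 0.626 with an estimated correlation). Macrophage or dendritic markers (6 of 6, median -0.83, camera adjusted p = 0.0178) and the markers shared by luminal cells (6 of 6, median -0.46, camera adjusted p = 0.0268) were also below 0, both at adjusted p = 0.626 with an estimated correlation. Cxcl1 was at 5759, 2236, 601 and 543 CPM and Cxcl2 at 960, 275, 100.1 and 32.8 CPM in fibroblast-like cells of the control and Zeb1 MSKO libraries at 8 weeks and those at 9 weeks. Heat shock genes Hspa1a (581 ± 52.1 to 219 ± 58.8 CPM) and Hsph1 (128 ± 8.65 to 32.5 ± 5.42 CPM) also fell. Mammary stem cell associated genes had a median of -0.40 (1 called lower, camera adjusted p = 0.00595) and contractile genes a median of 0.50 (0 called, camera adjusted p = 0.000326), both at adjusted p = 0.582 with an estimated correlation. In luminal progenitor-like cells edgeR called 95 genes (5 higher, 90 lower) and DESeq2 503 (68 higher, 435 lower). edgeR called 930 there with no filter on low counts, 62 without the Zeb1 MSKO library at 8 weeks, and 291 and 238 without the control or Zeb1 MSKO library at 9 weeks. In hormone-sensing luminal-like cells edgeR called 11 genes (0 higher, 11 lower), of which Cebpb was still called with genotype as a block (edgeR adjusted p = 0.0378), the only gene called in that fit. The other calls were lost, with Dapk3, Cxcl2, Akirin2, Alyref, Mtch1 and Ccl2 at an adjusted p of 0.0890 each. In these cells 8 of 8 fibroblast markers were below 0 (median -4.32, camera adjusted p = 6.72e-09; adjusted p = 0.646 with an estimated correlation). In this class DESeq2 called 403 genes and edgeR 197 with no filter on low counts. Leaving out the control or Zeb1 MSKO library at 8 weeks gave 5 and 1 genes, and leaving out those at 9 weeks 29 and 0. Of the genes lower in basal-like and luminal progenitor-like cells 64 were shared, where independent lists would share 1.29. Because all classes come from the same 4 libraries, part of that excess may come from shared library effects, and age cannot be told apart from preparation.

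**Figure D4:**
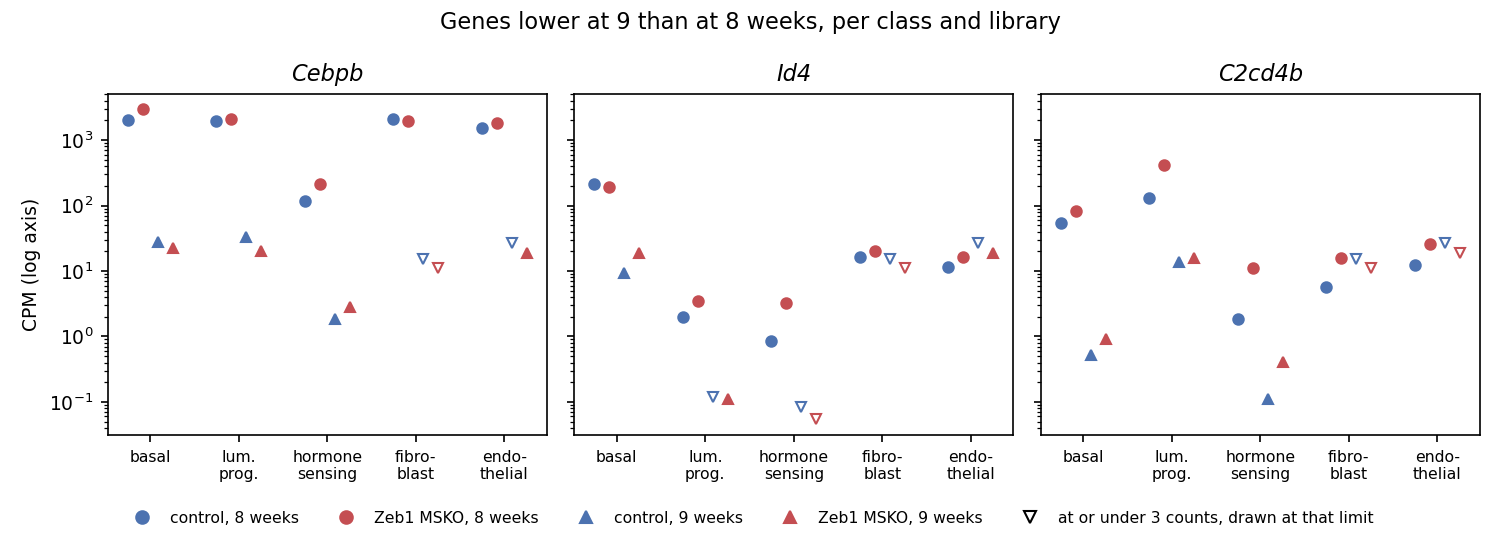
Levels (CPM, log axis) of genes lower at 9 than at 8 weeks in basal-like cells, shown per library in the 3 epithelial classes and in fibroblast-like and endothelial-like cells; open downward triangles mark values at or under 3 counts, drawn at that limit. Cebpb fell from 2580 to 24.7 CPM in basal-like cells and was also lower at 9 weeks in the other classes.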

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

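The tests on the basal-like share in this part, the comparison of cell-cycle lists between ages and the choice of the cycling clusters were made after the results were seen; the test of Cdh13 was fixed before the data were examined. Differences of shares and of list medians between ages were not tested, since each age has 1 library per genotype.

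The basal-like share of epithelial cells was 42.4 percentage points higher in the Zeb1 MSKO than in the control library at 8 weeks and differed by -1.6 points at 9 weeks. Doublet and cell filters are argued against by a move of at most 0.3 points when they were dropped. A different composition of the sorted suspension may have raised the share: the same library held 387 cells of an unnamed cluster with hair-follicle keratins (Krt71, Krt25, Krt28) against 8 in its control and 0 in both libraries at 9 weeks, and it differed from its control by 48.4-fold in that cluster, the highest of 11 clusters outside the epithelial classes. The median over the 11 was 1.37-fold and 2 differed by over 2-fold. Loss of Zeb1 stays open: the basal-like share of the Zeb1 MSKO library at 9 weeks was 27.9%, but 1 library per genotype and age cannot decide, and an effect of the genotype that depends on age or on the animal was not tested.

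The hormone-sensing luminal-like share differed by -16.1 points at 8 weeks and 3.1 points at 9 weeks. The share of basal-like cells with luminal keratins differed by 1.7 points at 8 weeks and -14.1 points at 9 weeks.

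Cell-cycle lists had opposite directions at the 2 ages in 2 classes. In basal-like cells the S phase median log2 ratio of Zeb1 MSKO to control was -0.93 at 8 weeks and 0.93 at 9 weeks, and the G2 and M phase median -2.19 and 1.49. In luminal progenitor-like cells these were -1.47 and 1.01 for S phase and -2.67 and 0.55 for G2 and M phase. Other lists, not listed here, also had medians of opposite sign at the 2 ages. Cluster 12, led by Csn3 and Wfdc18 with the cell-cycle genes Stmn1, Ube2c and Birc5 also among its 10 leading genes, held 9.11% and 0.971% of luminal progenitor-like cells in the control and Zeb1 MSKO libraries at 8 weeks and 1.43% and 3.10% at 9 weeks.

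The Cdh13 genotype effect differed between basal-like and hormone-sensing luminal-like cells by 3.16 on the log2 scale, the 1 gene called by edgeR's interaction test.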

How the results depend on the processing

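Other classes for the age comparison, genotype as a block beside age, genes of the highest GC content left out, the crossed split of the libraries and leaving out libraries from the age comparison were chosen after the data were seen. The causes of the changes below were not tested. DESeq2 called 1 basal-like, 7 luminal progenitor-like and 40 hormone-sensing luminal-like genes against 0 each, and 666 genes for age in basal-like cells against 191. With no filter on low counts edgeR called 19, 82 and 0 genes, and 107 in the basal minus hormone-sensing luminal interaction against 1. With age as a replicate block there were 12, 0 and 1 genes and 7 basal-like lists against 3, and the age comparison with genotype as a block called 544 basal-like genes, 5 basal-like lists against 3, with 48 members against 17, and 1 hormone-sensing luminal-like gene against 11, with 0 list members against 2. Of the list members adjusted over the list alone, 5 basal-like, 10 luminal progenitor-like and 7 hormone-sensing luminal-like were called with the age block, against 1, 0 and 4. With the age block 14 luminal progenitor-like and 12 hormone-sensing luminal-like lists were called against 12 and 11. Classes by marker score gave 5 basal-like lists and 0 interaction genes. With an estimated correlation 0, 0 and 0 lists were called. The age comparison called 95 genes in luminal progenitor-like and 11 in hormone-sensing luminal-like cells.

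Leaving out each library in turn gave 0 to 1 luminal progenitor-like and 0 to 1 hormone-sensing luminal-like genes. The lists called ranged from 4 to 7 in basal-like, 2 to 17 in luminal progenitor-like and 2 to 14 in hormone-sensing luminal-like cells. List members called when adjusted over the list alone ranged from 0 to 26, 0 to 30 and 0 to 45 in the same classes. The interactions gave 0 to 2 and 20 to 397 genes, and the age comparison 104 to 1536 in basal-like, 62 to 291 in luminal progenitor-like and 0 to 29 in hormone-sensing luminal-like cells. The genotype difference ranged from -17.2 to 4.24 points for the hormone-sensing luminal-like share and from -14.8 to 2.41 for the keratin share, changing sign without the Zeb1 MSKO library at 8 weeks and at 9 weeks, respectively. A 2 against 1 fit assumes that the lone library varies like the others.

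The basal-like and luminal progenitor-like shares kept their direction in all alternatives run, and leaving out any 1 library left 0 basal-like genes called. Counting each named gene once per alternative, 34 values passed where the reported one did not, 12 lost the call and 0 changed direction. These genes were chosen on the same libraries, by small p or by 1 direction in both genotypes. A kept direction is therefore not independent support. The split crossing age and genotype gave 0 genes in each class (477, 516 and 370 at an unadjusted p under 0.05). Clusters without the genes called between genotypes were not run, since edgeR without a block called none; the genes called by DESeq2 or with the block were not left out of the clustering. Depth limits genes near 3 counts per class.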

Other observations

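The GC content and stromal RNA tests below were written before their results were seen, and the others after them.

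Small clusters outside the mammary epithelium differed in number between the ages. An unnamed cluster with fast skeletal muscle genes (Acta1, Tnnc2, Ckm) held 10, 12, 0 and 0 cells in the control and Zeb1 MSKO libraries at 8 weeks and those at 9 weeks, a mixed immune cluster (Jchain, S100a8, Ccl5) 61, 42, 14 and 16, and a stromal cluster of chemokine genes (Cxcl13, Ccl7, Ccl2) 32, 53, 3 and 0. Some small clusters within the epithelial classes also took different shares. Cluster 23 of the basal-like class, led by Actg2 and Krt15 with Stmn1 among its 10 leading genes, held 34, 1, 10 and 15 cells (1.89%, 0.020%, 0.477% and 0.605% of the class), and cluster 22 of the hormone-sensing luminal-like class, where the S and the G2 and M phase lists were called higher in Zeb1 MSKO, led by Upk3a and Cited1 with the cell-cycle gene 2810417H13Rik among its 10 leading genes, held 1, 5, 6 and 61 (0.039%, 0.443%, 0.256% and 1.90%). Its leading genes include Wfdc12, which DESeq2 called between genotypes in this class, so its size is not independent of that difference.

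Milk and secretory genes were higher at 9 than at 8 weeks in luminal progenitor-like cells, with 14 of 18 positive and a median log2 fold change of 0.71 (camera adjusted p = 0.00383; adjusted p = 0.765 with an estimated correlation). Lalba, which encodes the milk whey protein alpha-lactalbumin, rose from 24.2 ± 7.33 to 160 ± 34.9 CPM (SD, n = 2 each; 2.71, SE 0.29; edgeR adjusted p = 0.0304) and the Notch target Hey1 from 52.0 ± 1.99 to 146 ± 2.49 CPM (1.48, SE 0.17; edgeR adjusted p = 0.0340). In the same cells the inflammatory cytokine Tnf fell from 103 ± 39.7 to 12.6 ± 4.66 CPM and the chemokine Ccl2 from 13.0 ± 0.378 to 0.685 ± 0.121 CPM (edgeR adjusted p = 0.0395 and 0.0103). Another called member of the milk list, Glycam1, fell from 7.66 ± 2.35 to 0.248 ± 0.0512 CPM (edgeR adjusted p = 0.0172); it is also among the leading genes of the endothelial-like clusters 17 and 19. Of the fibroblast markers 8 of 8 were below 0 in luminal progenitor-like cells at 9 weeks (median -3.85, camera adjusted p = 7.48e-08; adjusted p = 0.585 with an estimated correlation) and 4 of 4 endothelial markers (median -2.06, camera adjusted p = 5.24e-05; adjusted p = 0.563 with an estimated correlation), and Ccl2 is among the leading genes of the fibroblast-like cluster 11. As in basal-like cells, age cannot be told apart from preparation here.

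The genes lower at 9 than at 8 weeks in basal-like cells, led by Cebpb, were also lower in other classes. High GC content of their transcript ends is argued against, since their median lay -1.4 percentage points from that of expression-matched genes. Low GC content was not part of that prediction. Across all tested genes the age log2 fold change rose weakly with end GC (Spearman rho 0.182 in basal-like, 0.156 in luminal progenitor-like and 0.12 in hormone-sensing luminal-like cells). Free RNA from stromal cells is argued against for the set as a whole, since the median log2 ratio of stromal to basal-like level was -0.05. It stays open for 10 of the 180 genes, at least 8 times more abundant in fibroblast-like or endothelial-like cells. A change of the basal cell state alone is argued against for 114 of the 180 genes, by their median log2 ratio of -1.07 in fibroblast-like cells. These genes had at least 20 CPM there at 8 weeks, and the 9-week libraries held only 25 and 33 such cells. For the other genes it stays open. Of the genes lower at 9 weeks in basal-like cells 21.8% have a longest transcript with 1 exon, against 6.15% of matched genes (permutation p = 0.0001, the smallest 10000 random sets can give), a hypothesis found and tested on the same data. A difference in dissociation, RNA handling or batch between the ages, and age itself in all cell types, stay open and cannot be told apart in this design.

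Only 3 genes differed by over 2-fold in 1 direction in all 3 epithelial classes and at both ages: Sbp lower and AY036118 and Rps26-ps1 higher in Zeb1 MSKO libraries, with as many (3) in the split crossing age and genotype. Rps26-ps1 (94.3, 270, 59.6 and 214 CPM in basal-like cells) is named as a pseudogene of Rps26 (1920, 1886, 1871 and 2274 CPM), and whether the counting divided reads between them was not tested, so its count is uncertain. Free RNA could account for the traces of Sbp outside hormone-sensing luminal-like cells, since its lowest class level was 0.006 of its highest. It does not bear on the difference within those cells, where Sbp was at 83.25, 0.42, 212 and 1.01 CPM. For the other genes free RNA is argued against by a ratio of 0.84. Linked strain variants gave a permutation p of 1.0 with 3 genes, which is too few to decide. Loss of Zeb1 in epithelial cells alone stays undecided, since only 2 of these genes, Rps26-ps1 and AY036118, were measured in fibroblast-like cells, too few to decide. Their median oriented log2 ratio there was 1.36 at 8 weeks. At that age Rps26-ps1 was at 70.42 (control) and 228.95 CPM (Zeb1 MSKO) in fibroblast-like and 77.1 and 184.45 CPM in endothelial-like cells. AY036118 was at 8.1 and 22.97 CPM in fibroblast-like and 8.76 and 24.04 CPM in endothelial-like cells. Both genes were also higher at 9 weeks, where some control values were at or under 3 counts. Sbp was at or under 3 counts in these cells, so it cannot decide.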
